A study of Mus musculus with 18 samples.

How the data were processed

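RNA of mouse epiblast stem cell (EpiSC) lines had been hybridised to 1-colour Illumina BeadChips as biotin-labelled cRNA. EpiSC are pluripotent cells grown from the epiblast of the post-implantation embryo. Per the labels, the embryos were of the B6D2 strain at the pre-streak or early streak stage, and the cells were kept in defined medium with 20 ng/mL activin A and 12 ng/mL FGF2. The 18 arrays hold 6 lines with 3 biological repeats each. FT.1, FT.2 and FT.3 came from fertilized embryos. NT.1, NT.2 and NT-LE came from somatic cell nuclear transfer embryos. The embryo of NT-LE is described in the labels as having a large extra-embryonic ectoderm, and the other embryos as normal. The cell type that gave the donor nuclei is not given in the sources used here. All 18 arrays were placed in their line by their titles, and 0 data columns were left unmatched.

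The authors deposited a table of probe signals before normalization, in intensity on a linear scale, with 45281 probes. It was used here without detection p-values or control probes. The authors also deposited a table of processed values that lie on a log2 scale, judging by their range. The submitters' processing notes name BeadStudio and lumi, with no version, role or order. Each column of the processed table had a median of 7.93755 and a rank correlation of 1 with the signal of the same array. Its scale is therefore ordered like the signal and common to all arrays. The transformation behind it is not given in the sources used here, and it served only as an alternative.

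Because the background estimate planned for these arrays needs detection p-values or negative control probes, 1559 probes for chemosensory receptors (olfactory, vomeronasal, taste and trace amine receptors) took their place. This replacement was chosen after the tables were opened. The detection p of a probe is the share of receptor probes at least as bright on the same array. A receptor transcribed in these cells would make the background too high, and 127 receptor probes passed the filter below. Values were background-corrected with the nec function of limma 3.58.1 on R 4.3.3 with an offset of 16, then quantile-normalized and taken as log2. Probes with a detection p under 0.05 on at least 3 arrays were kept, which left 23268.

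Genes were named from the platform annotation. Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. The gene identifiers of 34807 probes matched a RefSeq table of assembly GRCm38.p6, which was used only to update symbols and for the order of genes along chromosomes. The probe with the highest mean log2 value stood for each gene, and unnamed probes stayed in the tests as themselves. The tests covered 15988 features, of which 12155 were named genes and 3833 were unnamed probes. No named probe was found here for T, H19, Snrpn or Ddx3y. Dppa3, Sox1, Pax6, Dnmt3a and Dazl did not pass the filter.

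The main test of origin averaged the 3 repeats of each line and compared 3 NT with 3 FT line means in limma (lmFit and eBayes). An embryo-derived line is the independent unit of origin. A second fit used all 18 arrays with 1 mean per line. It gave the contrast of NT with FT lines, the contrast of NT.1 and NT.2 with the FT lines, the contrast of NT-LE with NT.1 and NT.2, and all pairs of lines. Its error is the spread between repeats, so its p-values describe these 6 lines only. P-values were adjusted by Benjamini-Hochberg and called under 0.05. A 2-fold bound was added for pairs of lines. Genes were also counted that were called in the same direction in all 9 pairs of an NT with an FT line. Distances between lines were root mean square log2 differences, tested by an exact permutation over 10 splits of the lines. Shares of variance for origin, line and repeat came from a nested analysis per gene with negative components set to 0.

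The rule for named genes, the tests and 21 gene lists were fixed before the data were examined. The lists cover primed and naive pluripotency, primitive streak and mesoderm, endoderm, neuroectoderm, extra-embryonic ectoderm and trophoblast, germ cell genes, imprinted genes, sex-linked markers, DNA methylation and chromatin, activin, Nodal and FGF signalling, BMP and Wnt targets, fibroblasts and mesenchyme, cumulus and granulosa cells, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, the amino acid stress response, p53 targets, proliferation, and interferon response with MHC class I. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry for the origin contrast. Named for origin are up to 15 genes per direction called with lines as replicates, filled to 10 with genes called in all 9 pairs, ranked by the smallest of the 9 differences. Named for NT-LE are the 10 higher and 10 lower genes with the largest smaller difference from NT.1 and NT.2. Each of the other 5 lines has the 4 genes furthest from all other lines. A fixed set of pluripotency, lineage, imprinted and sex-linked genes is reported whether called or not. Each list gives its called members or, with none called, up to 4 members with the largest differences. Clone-like symbols were counted but not named.

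A gene was treated as not above background in a line when all its probes were undetected on all 3 arrays of the line. It then has only a bound. The bright group's mean was set against, per array, the higher of the dim probe's value and the lowest value among detected probes, and the ratio is given as at least that fold.

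The fits were tested on simulated data with 15988 features, of which 67, 67 and 66 were changed by 0.5, 1 and 2 log2. With lines as replicates, 13.4% of changes of 0.5 log2 were recovered, 67.2% of changes of 1 log2 and 90.9% of changes of 2 log2. The 18-array fit recovered 83.6%, 98.5% and 100%, and the count over all 9 pairs 11.9%, 73.1% and 93.9%. Of 15788 unchanged features, 5 were called with lines as replicates, 12 in all 9 pairs and 1300 by the 18-array fit. The last count includes the simulated differences between lines, which that fit does not separate from origin. Simulated line effects were normally distributed and independent between genes. Recovery in the real data can therefore be lower, and few genes called there would not show that few genes changed.

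Alternatives to the processing were the authors' table, no background correction, an offset of 50, cyclic loess, no filter, a strict filter (detection p under 0.01 on all 18 arrays), every probe on its own, sex-linked genes left out, other error models, other bounds, a replicate block, and each array and each line left out. Normexp fitted on all probes, 3 arrays left out, chromosome 11 left out and the imprinted list left out were added after the data were seen. Figures were drawn with Python 3.11.15.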

Results

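Expression was measured on 18 arrays from 6 mouse EpiSC lines, with 3 biological repeats per line. Lines FT.1, FT.2 and FT.3 derive from fertilized embryos and lines NT.1, NT.2 and NT-LE from embryos made by somatic cell nuclear transfer. Each line comes from 1 embryo, so 3 lines stand for each origin. Mean signal ran from 636.23 to 791.63 on FT arrays and from 682.18 to 1141.9 on NT arrays. The 95th percentile of signal over the receptor-probe median was 24.49 to 30.7 on FT and 27.64 to 37.65 on NT arrays, so brightness before normalization moved with origin. Between 43.02% and 46.29% of probes were detected per array. Correlations between repeats of a line ran from 0.98077 to 0.99556. The small number of lines limits the precision of each statement on origin.

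The first question was whether lines from cloned embryos differ from lines from fertilized embryos. Zdbf2, a paternally expressed imprinted gene, stood at 9.85 ± 0.06, 10.19 ± 0.12 and 10.13 ± 0.21 in FT.1, FT.2 and FT.3 (log2, SD, n = 3). In NT.1, NT.2 and NT-LE it stood at 5.27 ± 0.36, 5.20 ± 0.09 and 6.48 ± 0.21. It was not above background in NT.2, at least 22.8-fold below the FT lines. Capn11, a calpain protease gene, was detected on all 9 NT arrays and on 0 FT arrays, at least 1.37-fold higher in NT lines. Cyb5b, which encodes a cytochrome b5 of the outer mitochondrial membrane, was lower in NT lines by a log2 difference of -0.87 (SE 0.08, n = 3 lines per origin). With lines as replicates these 3 genes missed the threshold: the adjusted p in limma was 0.0656 for Zdbf2, 0.0656 for Capn11 and 0.0715 for Cyb5b. No gene of 15988 was called (0), while 2128 had an unadjusted p under 0.05 against 799.4 by chance and 294 to 1783 in the 9 other splits of these lines. Other processing settings called up to 3 genes, Zdbf2, Cyb5b and Capn11, and leaving out NT.1 gave 18 and FT.3 gave 5. Fits that count arrays called 582 with line as a random block and 1939 with 9 against 9 arrays.

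Over these 6 lines, with the spread between repeats as the error, 3340 genes passed, 1840 higher and 1500 lower in NT lines. The excess of higher genes depends on processing and lines: cyclic loess gave 1732 higher and 1747 lower, and leaving out FT.1, FT.2 or NT-LE gave 930 and 985, 871 and 948, or 1017 and 1058. With chromosome 11 left out 1741 were higher and 987 lower. A 2-fold difference as well was seen for 100, of which 24 were higher and 76 lower. Genes that differed in the same direction in all 9 pairs of an NT with an FT line numbered 28, with 7 higher and 21 lower, and 25 of them had usable names. This fit describes these lines and not origin, and without NT.1 the count over pairs was 223, without FT.3 172, without NT-LE 47 and without NT.2 46. It was 18 without FT.1 repeat 3, FT.2 repeat 3 or NT.2 repeat 2.

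Of the genes higher in every NT line, Gusb, the lysosomal beta-glucuronidase, differed by 2.31 (log2, SE 0.09) and skeletal muscle actin Acta1 by 2.01 (SE 0.19). Acta1 lay at 6.20 to 6.26 in FT lines and at 8.96, 7.40 and 8.36 in NT.1, NT.2 and NT-LE. Sgip1 rose by 1.38, the scavenger receptor gene Scarf2 by 1.16 (0.75 without FT.1) and the collagen chaperone Serpinh1 by 0.51. Of the genes lower in every NT line, Nmral1, the membrane serine protease gene St14 and the kinase gene Mapk13 were not above background in NT.2, at least 39.3-fold, 20.8-fold and 7.01-fold below the FT lines. In NT.1 and NT-LE, Nmral1 was at 7.68 and 9.49 against 10.16 to 11.54 in FT lines, St14 at 8.87 and 7.42 against 9.88 to 10.01, and Mapk13 at 7.17 and 6.65 against 7.98 to 8.68. The peroxidase gene Gpx7 was not above background in any NT line, at least 4.49-fold below the mean of the FT lines and at least 1.35-fold below FT.2, the lowest of them. Foxa3, an endoderm transcription factor, was not above background in NT.1, at least 4.63-fold below the FT lines, and at 5.46 and 5.54 in NT.2 and NT-LE. The NT minus FT difference was -2.13 and -1.41 (log2) for the aldo-keto reductases Akr1b10 (-1.17 without NT.1, where it is lowest) and Akr1b8 and -1.25 for the immunoproteasome subunit Psmb8. Adjusted p in the 18-array limma fit ran up to 9.01e-06 among these genes (Psmb8). With lines as replicates it lay between 0.316 and 0.341, so the differences hold for these lines only.

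**Figure D1:**
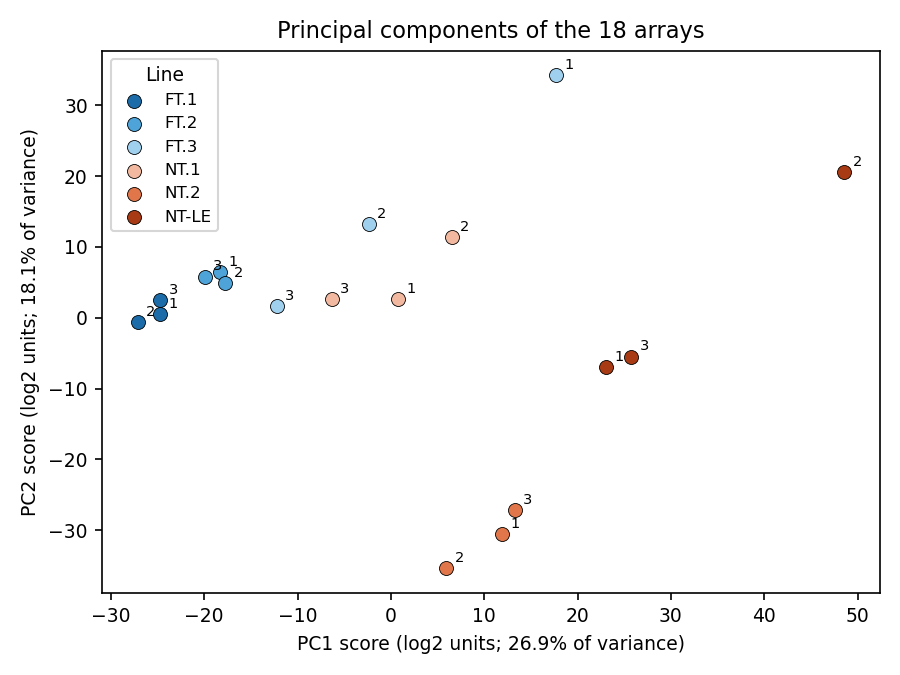
Principal components of the 18 arrays over all genes tested, with component 1 (26.9% of variance) on the x axis and component 2 (18.1%) on the y axis, 1 point per array and 1 colour per line. FT.1, FT.2 and NT.2 form tight groups of repeats, while FT.3 replicate 1 and NT-LE replicate 2 lie away from the other repeats of their lines.

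Genes of the amino acid stress response, targets of the transcription factor ATF4, were higher in NT.2 and NT-LE as a group, but not in NT.1. Of 28 measured, 18 rose, 1 fell and 9 did not pass in the 18-array fit of NT against FT lines, and adjusted over the list alone 20 rose and 1 fell. Chac1, which degrades glutathione, rose by 0.89 (SE 0.14), Cth of cysteine synthesis by 0.85 (SE 0.19) and the mitochondrial folate enzyme Aldh1l2 by 0.69 (SE 0.08). NT.2 carries much of this: Chac1 was at 10.73, 12.62 and 11.75 in NT.1, NT.2 and NT-LE against 10.25 to 11.11 in FT lines, and Aldh1l2 at 5.58, 7.73 and 6.07 against 5.41 to 6.18. Without NT.2 the differences of Chac1, Cth and Aldh1l2 were 0.43, 0.61 and 0.05, and none of them passed. The cystine transporter Slc7a11 was at 5.93, 7.33 and 7.29 in NT.1, NT.2 and NT-LE, at 6.17 and 6.96 in FT.2 and FT.3, and its probe was undetected in FT.1. Ddit4, an inhibitor of mTOR signalling, was the member that fell (-0.39). Line by line against the FT lines, 22 members rose in NT.2 and 14 in NT-LE, with 0 falling in either, and in NT.1 1 rose and 1 fell. The list medians were 0.666, 0.32 and 0.0979 in NT.2, NT-LE and NT.1. The list was called with lines as replicates (camera adjusted p = 0.00018), but not with an estimated correlation (adjusted p = 0.985) or by fry (adjusted p = 0.575).

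Interferon response and MHC class I genes were lower in NT lines as a group. Of 27 measured, 12 fell, 1 rose and 14 did not pass, and adjusted over the list alone 14 fell and 1 rose. Line by line against the FT lines, 3 members fell in NT.1, 13 in NT.2 and 7 in NT-LE, where 3 rose. With a 2-fold bound 0 fell in NT.1, 8 in NT.2 and 2 in NT-LE, and 0 rose. The list medians were -0.215 in NT.1, -0.408 in NT.2 and -0.13 in NT-LE, and the list was still called without NT.2. The log2 difference was -1.25 (SE 0.13) and -1.02 (SE 0.08) for the immunoproteasome subunits Psmb8 and Psmb9 and -0.98 (SE 0.10) for Ifi35. Psmb8, Psmb9 and H2-K1 lie on chromosome 17. The class I gene H2-K1 was not above background in NT.2, at least 8-fold below the FT lines, while NT-LE stood at 9.45 against 8.47 to 8.61 in FT lines, and without NT.2 its difference turned to 0.35. A second H2-K1 probe lay at 7.65 in FT.2 and at 5.01 to 5.46 in the other lines. Strain differences under these probes were not tested. Psmb9 was low in NT-LE, at 5.72, and lay at 7.69 to 8.22 in the other lines. The list was called with lines as replicates (camera adjusted p = 0.00557), but not without FT.3, with an estimated correlation (adjusted p = 0.985) or by fry (adjusted p = 0.575). Adjusted over the list alone with lines as replicates, 1 member passed, and over all genes 0.

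Imprinted genes moved in both directions. Of 47 measured, 11 rose, 11 fell and 25 did not pass in the 18-array fit, and adjusted over the list alone 12 rose and 12 fell. Against the FT lines, 1 rose and 4 fell in NT.1, 10 rose and 11 fell in NT.2, and 10 rose and 10 fell in NT-LE. The paternally expressed genes Ndn, Peg3, Mest, Mkrn3 and Impact were not above background on any array of NT.2 or NT-LE. They lay at least 94.7-fold, 94.5-fold, 87.5-fold, 11.1-fold and 63.7-fold below the mean of the FT lines in NT.2, and at least 95.3-fold, 95.2-fold, 88.1-fold, 11.1-fold and 64.2-fold below in NT-LE (for Impact at least 21.3-fold and 21.4-fold below FT.1, its lowest FT line). NT.1 kept them at 11.90 ± 0.17 for Ndn, 12.40 ± 0.23 for Peg3 and 12.40 ± 0.14 for Mest (log2, SD, n = 3), against 12.03 to 12.22, 11.93 to 12.22 and 11.74 to 12.23 in the FT lines. Peg10, a placental retrotransposon-derived gene, lay at 5.41 and 5.37 in NT.2 and NT-LE and at 7.07 to 7.60 in the other lines. The maternally expressed cell cycle inhibitor Cdkn1c was at 8.40 in NT.2 and 9.77 in NT-LE, at 5.67 to 7.18 in FT lines and not above background in NT.1. Over the 6 lines the paternally expressed Igf2 lay at 11.82 to 12.61 and Dlk1 at 8.28 to 9.25, and the maternally expressed Meg3 at 5.84 to 6.75 and Rian at 6.80 to 7.68. The list as a whole was not called (camera adjusted p = 0.982), and its mean and median difference have opposite signs (-0.48 and 0.06), with the test pointing down. Camera tests for a shift in 1 direction, so it cannot decide on a list that moves both ways. In fry for change in either direction, only BMP and Wnt targets and germ cell genes ranked before the imprinted list. No call was made from that ranking. Adjusted over the list alone with lines as replicates 3 members passed, and over all genes 0.

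**Figure D2:**
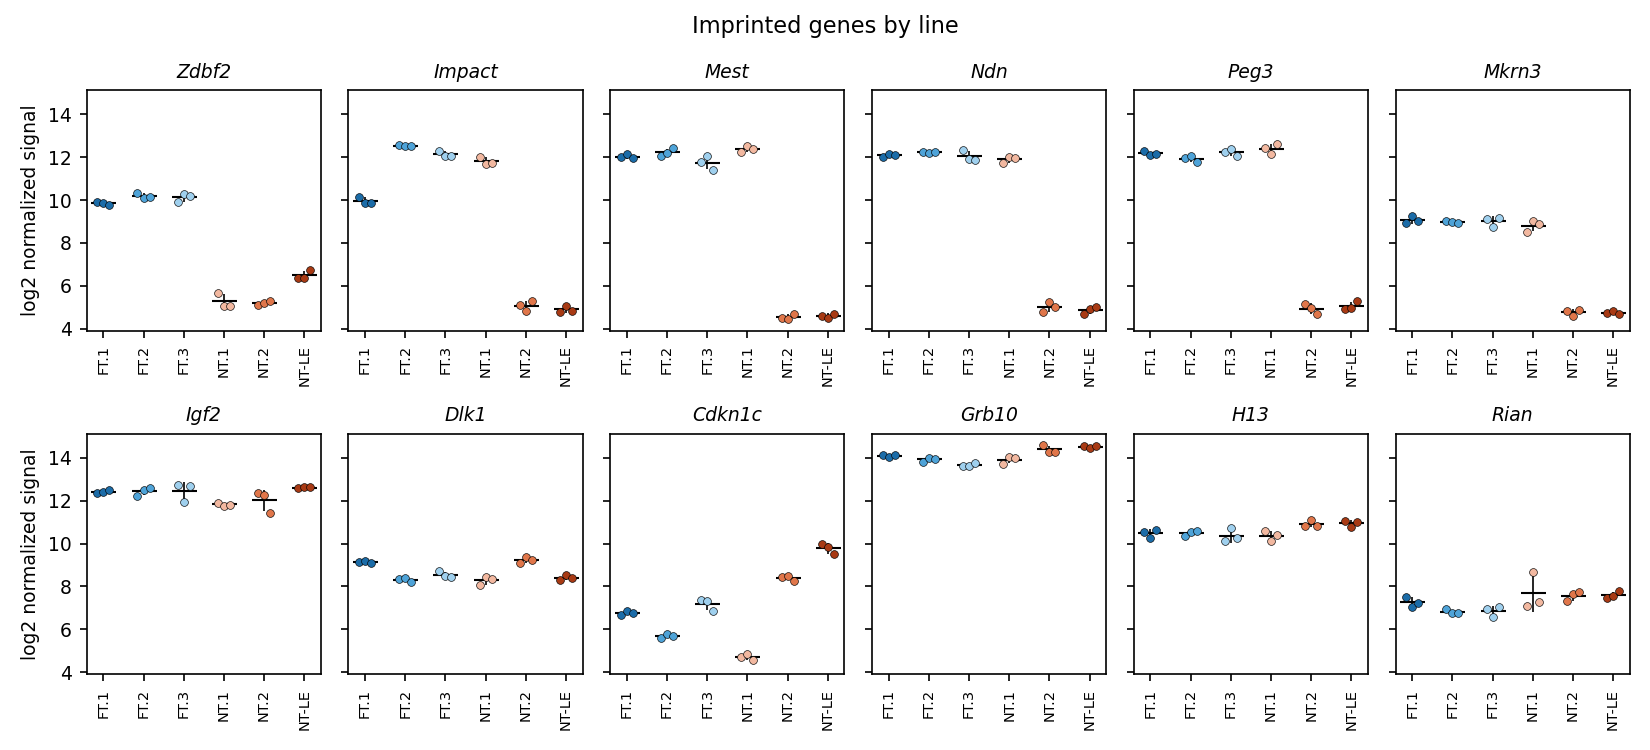
Log2 expression of 12 imprinted genes, chosen after their values were seen, in the 6 lines, with the log2 normalized signal on the y axis, 1 point per array, and a bar and whisker for the mean and SD of each line (n = 3). Ndn, Peg3, Mest, Mkrn3 and Impact are near background in NT.2 and NT-LE, and Zdbf2 is lower in the NT than in the FT lines.

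The pluripotency genes Pou5f1, Nanog, Sox2, Fgf5 and Dnmt3b were expressed in all lines, and whether their levels are equal was not tested. Pou5f1 lay between 13.68 and 14.22, Nanog between 11.56 and 12.12, Sox2 between 8.24 and 9.18, Fgf5 between 12.46 and 12.68 and the methyltransferase Dnmt3b between 14.95 and 15.30. Zfp42, Klf4 and Esrrb, markers of the naive state, lay at 5.79 to 6.32, 5.90 to 6.43 and 6.43 to 7.51. Pou5f1 was 0.22 (SE 0.06) and Nanog 0.31 (SE 0.09) higher in NT lines in the 18-array fit (adjusted p = 0.0224 and 0.0216), with adjusted p = 0.471 and 0.337 with lines as replicates, their other probes differ in direction, and neither passed without FT.2 or without NT.2. Of 23 primed pluripotency genes 4 rose and 3 fell (camera adjusted p = 0.982), and of 16 naive genes 1 rose and 3 fell (adjusted p = 0.982). Adjusted over the list alone, 4 rose and 3 fell among the primed and 3 rose and 3 fell among the naive genes. The naive list had a median of 0.02 and a mean of 0.02 while its test pointed down. Dnmt3l and Elf5 were detected on few arrays, at 4.96 to 5.34 and 5.05 to 5.56.

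Lineage genes differed little by origin as groups. Sox17 fell by 0.46 (SE 0.12) and Gata6 fell by 0.33 (SE 0.10) in NT lines in the 18-array fit (adjusted p = 0.0128 and 0.0281), but 20 of 24 endoderm genes did not pass, 1 rose and 3 fell, and neither Sox17 nor Gata6 passed without FT.1 or without NT-LE. Cer1 was at 11.96 to 12.45. The endoderm list had an adjusted p of 0.155 in camera but was called, as lower, without FT.1, without NT.1, without NT.1 repeat 2 or NT.2 repeat 1, and with every probe on its own. The list adjusted p was 0.982 for primitive streak and mesoderm (2 rose and 4 fell of 19), 0.982 for neuroectoderm (3 rose and 4 fell of 20) and 0.982 for extra-embryonic ectoderm and trophoblast (1 rose and 4 fell of 23). Of other cell types the cultures could carry, 5 of 20 fibroblast and mesenchyme genes rose and 1 fell (adjusted p = 0.982), and 2 of 14 cumulus and granulosa genes rose (adjusted p = 0.982). Krt19, a keratin of trophoblast and simple epithelia, fell by 2.59 (SE 0.20), to 5.74 in NT.2 against 9.58 to 10.35 in FT lines. In the primitive streak list Evx1 fell by 0.82 and Gsc fell by 0.49, and Pdgfra rose by 0.50, while without NT-LE the differences were -0.49, -0.27 and 0.28, and that of Pdgfra did not pass. Adjusted over the list alone, 0 endoderm genes rose and 3 fell, 3 streak genes rose and 4 fell, 5 neuroectoderm genes rose and 4 fell, 1 trophoblast gene rose and 4 fell, 5 fibroblast genes rose and 1 fell, and 2 cumulus genes rose. Median, mean and test differed in sign for the streak (0.08, 0.03 and down), neuroectoderm (0.02, -0.17 and down), trophoblast (0.04, -0.13 and down) and fibroblast lists (-0.00258, 0.09 and down).

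Sex-linked transcripts separated FT.1 and FT.2 from the other lines. The Y-linked Eif2s3y was at 10.59 ± 0.13 in FT.1 and 10.28 ± 0.10 in FT.2 (log2, SD, n = 3) and not above background in FT.3 and the NT lines. Kdm5d was at 7.16 and 6.98 in FT.1 and FT.2 and likewise not above background elsewhere. Xist, the X-inactivation transcript, was at 10.88 to 11.12 in FT.3 and the NT lines and at 4.52 in FT.1 and FT.2. Uty lay at 6.86 in FT.1 and FT.2 and 6.04 to 6.22 elsewhere. In the 18-array fit 1 of 4 markers rose and 3 fell in NT lines, and likewise adjusted over the list alone (camera adjusted p = 0.296, but the list was called without FT.3). With lines as replicates 3 passed adjusted over the list alone and 0 over all genes. Rhox5, an X-linked homeobox gene, stood at 5.85 in NT.1, 6.14 in NT.2 and 7.41 to 7.76 in the other 4 lines. Thus FT.1 and FT.2 had the pattern of male cells, while all 3 NT lines and 1 FT line had Xist signal and no Eif2s3y or Kdm5d above background. The comparison of origin is not balanced for sex.

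The next question was how far single lines differ. A 2-fold called difference separated 98 to 166 genes between pairs of FT lines, 238 to 384 between pairs of NT lines and 116 to 553 between an NT and an FT line. The means were 128.7, 305.7 and 292.3, and over all 6 pairs within an origin 217.2. Without FT.1 the order turned, with 244.5 between and 249 within origins, and in the authors' table the means were 55.33 and 41.17. NT.1 and FT.3 differed in 116 genes and NT-LE and FT.1 in 553. The root mean square distance was 0.396 log2 between origins and 0.352 within origins, 0.305 within FT and 0.399 within NT lines. The difference of 0.044 had an exact one-sided permutation p of 0.1, the smallest that 3 against 3 lines allow, with 0.0281 as the highest of the other splits. The median share of variance, taken over genes for each component on its own, was 65.1% between repeats, 15.5% between lines and 0% by origin. The means were 63%, 22.9% and 14%. Negative components were set to 0, so the median of 0% is not a measured absence of an origin share.

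**Figure D3:**
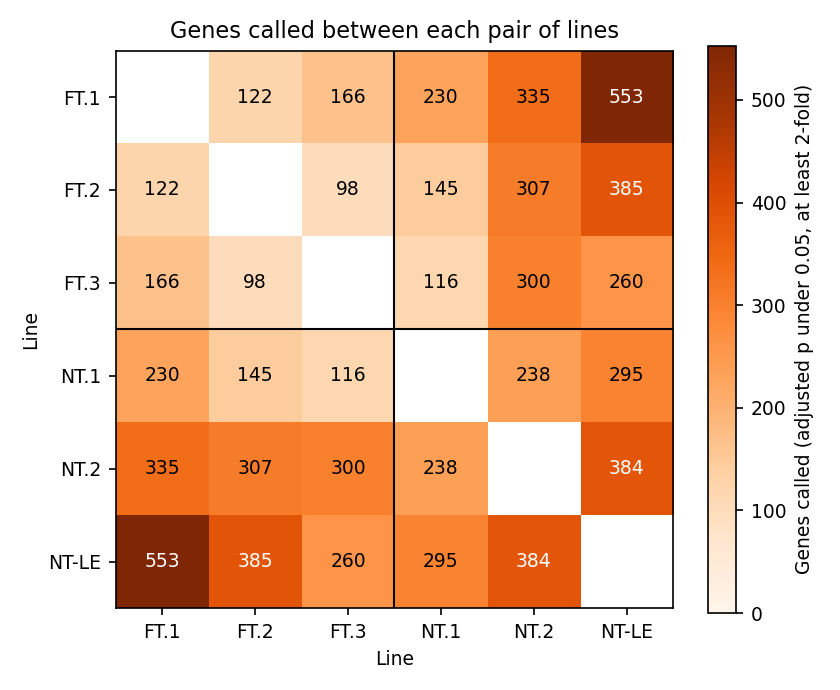
Grid of the 6 lines against each other, in which each cell gives in number and colour the genes called between 2 lines (adjusted p under 0.05, at least 2-fold), with black rules between FT and NT lines. Pairs of FT lines lie at 98 to 166 and pairs of NT lines at 238 to 384.

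Because NT-LE came from an embryo with a large extra-embryonic ectoderm, NT.1 and NT.2 were also set against the FT lines. Of 15988 genes 2087 passed, 1019 higher and 1068 lower (649 and 823 without NT.2 repeat 1), and 135 also differed 2-fold, 23 higher and 112 lower. The log2 difference of Zdbf2 from the FT lines was -4.79 (SE 0.13) in NT.1, and in NT.2 it has only the bound of at least 22.8-fold. Zdbf2 was about as low in NT.1 (5.27) as in NT.2 (5.20), so the size of the NT.1 difference is limited by the floor as well. Of these 2 lines only NT.2 lacked Ndn, Peg3 and Mest. Line by line with a 2-fold bound, 114 genes differed in NT.1 (46 higher, 68 lower), 258 in NT.2 (56 higher, 202 lower) and 317 in NT-LE (136 higher, 181 lower). Whether these lines differ in number of changed genes was not tested beyond the pairs above.

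NT-LE was then compared with NT.1 and NT.2. Acot1, a cytosolic acyl-CoA thioesterase, was at 12.39 ± 0.08 in NT-LE, 7.80 ± 0.14 in NT.1 and 9.30 ± 0.22 in NT.2 (log2, SD, n = 3), a rise of 3.84 (SE 0.13). The isomerase Pin4 rose by 3.70, the thyrotropin-releasing hormone gene Trh by 3.61, the neuronal gene Stmn2 by 2.97 and the midbrain transcription factors Lmx1a and En1 by 2.71 and 2.56. Stmn2 and En1 lay at 9.99 and 8.57 in NT-LE, within reach of the FT lines (9.93 to 10.13 and 7.68 to 9.10), and low in NT.1 and NT.2. Igfbp5 rose by 2.09. The extracellular matrix gene Mgp was not above background in NT.1 and NT.2, at least 3.47-fold and 3.5-fold below NT-LE, and Lmcd1 was not above background in NT.2, at least 4.6-fold below. Arg1 was at 7.74 in NT-LE and 5.39 in NT.1, and its probe was undetected in NT.2. Other genes were also near the FT lines in NT-LE: Pin4 was at 9.50 against 9.70, 9.59 and 5.80 in FT.1, FT.2 and FT.3, Trh at 14.58 against 13.74, 14.49 and 11.42, Mgp at 7.35 against 7.12 to 8.85 and Lmcd1 at 7.75 against 6.75 to 7.48. Acot1 (6.89 to 10.55 in FT lines), Lmx1a (5.91 to 7.22) and Igfbp5 (10.76 to 11.35) lay above every FT line.

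Of the genes lower in NT-LE, Apoa2, an apolipoprotein of high-density lipoprotein, was not above background and lay at least 6.46-fold below NT.1. The difference from NT.1 and NT.2 was -3.79 (log2, SE 0.15) for the complex I subunit Ndufb10, -3.58 (SE 0.09) for Wdr46 and -3.23 (SE 0.10) for Wdr82. It was -3.05 for Pdxdc1, -2.87 for Abhd16a and -2.76 for Ube2cbp. High values in NT.2 enlarge some of these differences. NT.2 lay at 10.94 for Ndufb10, 10.91 for Wdr46, 11.21 for Pdxdc1 and 8.91 for Abhd16a. NT.1 and the FT lines lay at 10.01 to 10.11, 9.94 to 10.01, 10.29 to 10.41 and 8.03 to 8.32. For Ube2cbp NT.2 (9.09) was not above them. The probe of the ceramide-phosphate transfer protein gene Cptp lay at 7.86 to 8.05 in the other 5 lines and was undetected on all 3 NT-LE arrays. The peptide transporter gene Slc15a2 and the malic enzyme gene Me1 were not above background in NT-LE, at least 2.88-fold and 3.72-fold below NT.1, and Slc15a2 was not detected in FT.2 either. Other probes of some of these genes gave different values. A second Ndufb10 probe was higher in NT-LE (10.16) than in NT.1 (9.68) and NT.2 (8.88), 2 of 5 Pdxdc1 probes went the opposite way, the other probe of Cptp stayed near background and the other 3 probes of Wdr82 lay at 7.75, 6.83 and 6.54 in NT-LE against 7.98, 6.99 and 6.82 in NT.1. Probe sequences were not used here, so a strain difference under a probe was not separated from loss of a transcript in single lines, as for H2-K1 and Gpx7. For Ndufb10 the second probe argues against loss of the whole transcript in NT-LE. For Pdxdc1 a probe at 8.35 in NT-LE, against 7.94 in NT.1 and 6.98 in NT.2, argues against it likewise. The differences of -3.79 and -3.05 thus hold for the probes used and not for these genes as a whole. A strain difference under these probes was not tested.

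Across all genes, 1354 passed between NT-LE and the mean of NT.1 and NT.2, 861 higher and 493 lower (526 and 425 without NT-LE repeat 2), and 292 differed 2-fold, 171 higher and 121 lower. Against both NT.1 and NT.2, 502 genes were called in the same direction, 301 higher and 201 lower. With 1 line of this morphology the test compares lines and not morphologies.

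Neuroectoderm genes were higher in NT-LE than in NT.1 and NT.2 as a group. Of 20 measured, 8 rose, 0 fell and 12 did not pass, and adjusted over the list alone 10 rose. Besides En1 and Stmn2, Gbx2 rose by 2.14 (SE 0.26). En2 was at 6.92 in NT-LE and not above background in NT.2, at least 2.59-fold below, and Zic1 was detected on 2 of 3 NT-LE arrays, at 6.33, and not above background in NT.1 and NT.2. In FT lines En2 lay at 6.31 to 6.85, Zic1 at 5.89 to 6.15 and Gbx2 at 8.08 to 8.44, against 10.18 for Gbx2 in NT-LE. Against the FT lines 6 members rose and 0 fell in NT-LE, 1 rose and 3 fell in NT.1 and 0 rose and 5 fell in NT.2, so low values in NT.1 and NT.2 carry part of the difference. The call (camera adjusted p = 1.1e-05) did not hold with an estimated correlation (adjusted p = 0.0767). Fibroblast and mesenchyme genes were higher too, with 8 of 20 rising, 0 falling and 12 not passing, and adjusted over the list alone 9 rose and 1 fell. The matrix gene Dcn rose by 1.17 and smooth muscle actin Acta2 by 1.09, and Tgfbi was at 6.89 in NT-LE and 5.47 in NT.2, with its probe undetected in NT.1. The call (adjusted p = 1.1e-05) did not hold with an estimated correlation (adjusted p = 0.151). Targets of p53 were lower (adjusted p = 0.0189), but not with chromosome 11 left out or with an estimated correlation (adjusted p = 0.0767). Of 20, 1 fell (Dcxr, -0.41) and 19 did not pass, and adjusted over the list alone 4 fell. Dcxr and another member, Ccng1, lie on chromosome 11.

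Extra-embryonic ectoderm and trophoblast genes did not pass as a list in NT-LE (camera adjusted p = 0.0914, and adjusted p = 0.842 with an estimated correlation), but were called, as higher, with no filter, with the strict filter and without NT.1 repeat 1, NT.2 repeat 1 or NT-LE repeat 3. Of 23, 7 rose, 2 fell and 14 did not pass, and adjusted over the list alone 9 rose and 2 fell. Cdx2 rose by 1.25 (SE 0.28, adjusted p = 0.00984), to 7.37 against 5.91 in NT.1 and 6.33 in NT.2, and Eomes fell by 0.57 (adjusted p = 0.0388). Krt18 passed as higher, but only for the low value of NT.2: it lay at 12.30 in NT-LE, 12.60 in NT.1 and 10.49 in NT.2. Elf5 was detected on 0 of 3 NT-LE arrays.

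Each line also had genes that set it apart from all other lines, 97 in FT.1, 29 in FT.2, 23 in FT.3, 41 in NT.1, 216 in NT.2 and 276 in NT-LE. In FT.1, the matricellular gene Ccn2 was low, at 7.58 ± 0.10 against 10.52 to 12.28 elsewhere (log2, SD, n = 3), and Shfl (8.67), Fbxw17 (9.61) and Dhdh (7.64) were high. Dhdh was not above background in the other lines, at least 4.22-fold below FT.1 in FT.2. In FT.2, the tetraspanin Tspan6 was low, at 8.48 against 11.99 to 12.34, as were Akr1e1 and Slc18b1, not above background there and at least 3.58-fold and 3.23-fold below the NT lines, and Mgst1 was high at 8.77. In FT.3, the hexosaminidase subunit Hexa was low, at 6.31 against 9.48 to 10.73, as were Ric3 (5.42) and Plin2, not above background and at least 6.52-fold below the NT lines, and Nptx2 was high at 7.06. In NT.1, the co-chaperone Bag3 was low, at 7.54 ± 0.78 against 11.96 to 12.71, Akr1b10 was at 7.31, Cyba was not above background, at least 12.8-fold below the mean of the FT lines and at least 4.73-fold below FT.1, the lowest of them, and Sdr39u1 was high at 7.40. In NT.2, Polr1b, a subunit of RNA polymerase I, was at 5.44 against 10.05 to 10.19, Slpi was not above background, at least 12.6-fold below the FT lines, H2-Q6 was at 4.79 against 8.20 to 9.27, and Adamts9 was at 6.07. A second Adamts9 probe showed no such loss in NT.2. A strain difference under the H2-Q6 probe was not tested.

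Gene order along chromosomes, looked at after the values were seen, set chromosome 11 apart. Its 1026 genes had a median NT minus FT difference of -0.21 log2, and 85.2% were lower in NT lines, against 38.4% to 45.5% on the other chromosomes. Line medians were 0.13 in FT.1, 0.13 in FT.2, 0.06 in FT.3, -0.01 in NT.1, -0.13 in NT.2 and -0.17 in NT-LE. Ifi35, Krt19, Stat3, Dcxr and Ccng1, named above or among the lists, lie on this chromosome.

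**Figure D4:**
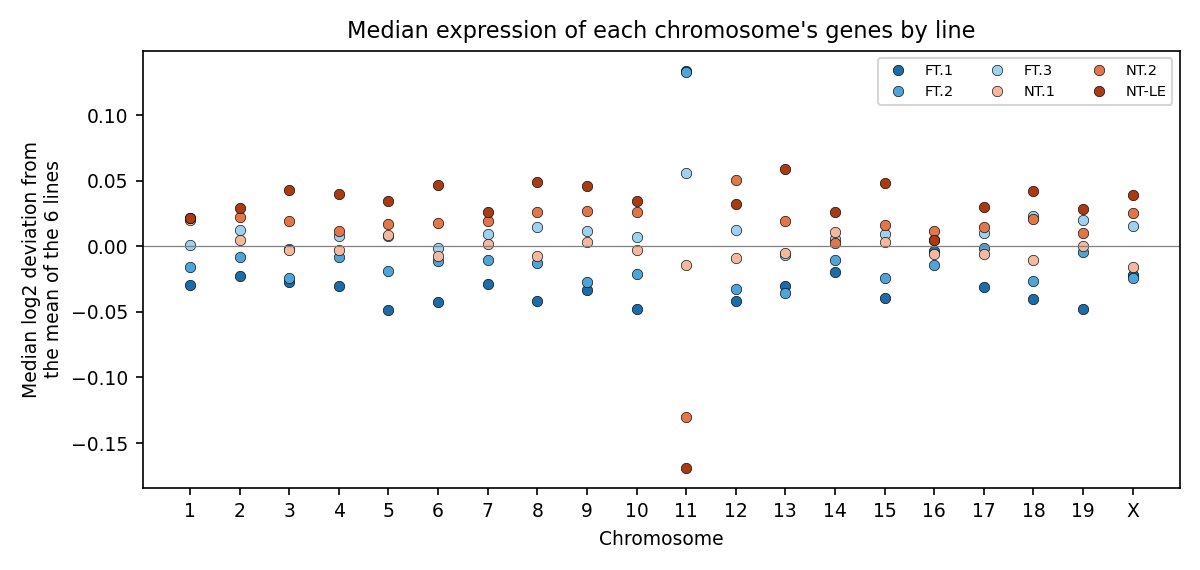
Median log2 deviation of each chromosome's genes from the mean of all lines, on the y axis in log2 units and the chromosome on the x axis, with 1 point per line and chromosome. Chromosome 11 runs from 0.13 in FT.1 to -0.17 in NT-LE, a range of 0.303, and the widest range of another autosome is 0.0948.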

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

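The tests of the 3 patterns below were chosen after the result was seen, except those of unlinked loss, of part of chromosome 11 and of array signal level, which were written down before their outcomes were seen. In 94 groups of 9 arrays of 1 origin, 6 values, on 4 arrays, lay further from the nearest other value than Dixon's ratio of gap to range allows, where about 4.7 are expected by chance. FT.3 replicate 1 had 43.02% of probes detected against 44.75% on the next FT array, a Cer1 value of 11.94 against 12.19 and a Meg3 value of 5.429 against 5.904. NT-LE replicate 2 had a root mean square deviation from its line mean of 0.2768 against 0.2146. Zfp42 was at 5.415 on NT.2 replicate 1 against 5.967, and Rian at 8.669 on NT.1 replicate 2 against 7.772.

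The first pattern is the loss of Ndn, Peg3, Mest and Mkrn3 in NT.2 and NT-LE, and background correction, failed arrays and failed probes of Mest and Peg3 are argued against. Without background correction the smallest gap to another line was 2.35 log2, and these 6 arrays had 44.33% or more of probes detected against 43.02% or more on the others. Each other probe of Mest and Peg3 that passed the filter was lower on every one of the 6 arrays than on every other array. The gap was 0.0932 log2 at the least and 4.11 to 6.25 for 3 of these 4 probes. The probes of Ndn and Mkrn3 did not fail on all arrays, since they read 11.9 to 12.2 and 8.79 to 9.07 in the FT lines and NT.1. Their failure in NT.2 and NT-LE alone stays open, since these genes have 1 probe each. The 4 genes were also picked for being detected 48 times of 48 on the 12 other arrays and 0 times on these 6. Maternally derived genomes only stay open. The median of maternally minus paternally expressed genes against NT.1 was 0.408 log2 in NT.2 and 0.518 in NT-LE (permutation p = 0.0071 and 5e-04, bootstrap SD 1.16 in NT.2). The 16 paternally expressed genes hold the lost ones, and without the 6 lost genes this difference was -0.0217 and 0.208 (permutation p = 0.53 and 0.11). Igf2 and Dlk1, paternally expressed, stayed high. Neither result decides the question. The lost genes were left out for being lost, and Igf2 and Dlk1 were picked after their values were seen. Of the paternally expressed genes left, Magel2, Kcnq1ot1, Rasgrf1 and Dio3 were low in every line and Zdbf2 was already low in NT.1. For the test of all 16 paternally expressed genes 3 decision rules were run after the result was seen: the bound of 0.5 alone argued against the explanation, the bound with the spread on 1 side went with it, and the rule kept, with the spread on both sides, leaves it undecided. Segments homozygous for 1 strain's allele and unlinked loss of single transcripts stay open as well, because their tests left out imprinted genes and held 0 of these 4 genes: among other genes 23.1% of probes lost in NT-LE were 0.5 to 1.5 log2 above the median line in NT.2, and neighbouring lost genes shared a line in 47.1% of 17 pairs (permutation p = 0.27), which says nothing on the pattern.

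The second pattern is the lower expression of chromosome 11 in NT lines. A trend with mean expression is argued against, since none of 10000 lists matched on expression had a median as low as -0.215 log2 (permutation p = 1e-04, the smallest they can give, with medians from 0.00674 to 0.0543). This p does not allow for the choice of chromosome 11 as the most extreme chromosome, and other normalization effects were not tested. The low median is not that of a few genes, since 85.2% of its genes were lower. That share helped to set the chromosome apart, so it is no separate test. A haplotype of part of the chromosome is argued against, since by position the 4 parts had medians of -0.231, -0.223, -0.17 and -0.23. A different copy number of chromosome 11 could account for the lower expression and stays a hypothesis: the widest line range of another autosome was 0.313 times that of chromosome 11, but the chromosome was picked for being extreme, copy number was not measured, and line and origin are not separable here. Single arrays spread most in FT.3 (-0.0264 to 0.132) and NT.1 (-0.113 to 0.0578), which a mixture of cells in these cultures might also give, and counting chromosomes in each line would test both.

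The third pattern is that FT.3 replicate 1, NT.1 replicate 2 and NT-LE replicate 2 deviated from their line means alike, with r of 0.669, 0.42 and 0.363 for their pairs and up to 0.393 for other pairs of arrays. The signal level of the array stays open. The rank correlation of the deviations with mean expression was -0.102, -0.0423 and -0.12 on these arrays, at most 0.12 in size. Quantile normalization had already removed most of such a trend from every array, and no other array reached 0.12 in size. The test therefore decides nothing on this pattern. Transcript integrity or another effect of probe position could account for it and stays open: the correlation between 2 probes of a gene was at most 0.435 times that of line differences, but in a control added after this was seen the 15 other arrays had correlations of 0.0737 to 0.363, and these 3 lay within them at 0.216 to 0.261. The labels give no biological difference between these arrays and their repeats, so none was tested. RNA integrity values of the 18 samples, not used here, would test it.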

How the results depend on the processing

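Normexp on all probes and leaving out 3 arrays, chromosome 11 or the imprinted list were tests chosen after the result was seen, and for each shift below the cause was not tested. Genes called by origin with lines as replicates, 0 by limma as reported (2128 at an unadjusted p under 0.05), were 2 with the authors' table, without background correction and with an offset of 50 (Zdbf2 and Cyb5b each time), and 3 with trend and robust eBayes and with normexp on all probes (Zdbf2, Cyb5b and Capn11). They were 582 with line as a random block (correlation 0.22) and 1939 with 9 against 9 arrays. They were 0 to 2 with an array left out (2 without NT.1 replicate 3, Zdbf2 and Capn11, and 1 without NT-LE replicate 3, Zdbf2). They were 0 to 18 with a line left out (18 without NT.1, 5 without FT.3 and 1 without NT-LE, Zdbf2). The 18 hold the imprinted genes Ndn, Peg3, Mest, Mkrn3, Peg10 and Zdbf2, and others such as Dlgap5, Chmp4c and Capn11. The 5 are Kdm5d, Eif2s3y, Xist, Cldn7 and an unnamed probe. These genes are named after their values were seen, and the adjusted p of Zdbf2 ran from 0.000486 without NT-LE to 0.495 without FT.2.

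In the 18-array fit 100 genes also passed the 2-fold bound, 2807 to 3637 passed with an array left out and 1819 to 4401 with a line left out (1819 without FT.2, 1915 without FT.1 and 2075 without NT-LE). Genes separating all NT from all FT lines were 18 with the strict filter and 6 with 2-fold differences. They were 18 to 29 with an array left out (18 without FT.1 replicate 3, FT.2 replicate 3 or NT.2 replicate 2) and 25 to 223 with a line left out (223 without NT.1, 172 without FT.3, 47 without NT-LE and 46 without NT.2). The 2-fold bound left 135 genes for NT.1 and NT.2 and 292 for NT-LE. With an array left out these comparisons, without the bound, gave 1472 to 2240 and 951 to 1517. Mean genes per pair between and within origins were 55.33 and 41.17 in the authors' table, 114 and 88.83 without background correction, 180.2 and 133.7 with an offset of 50, 113.4 and 78.17 with the strict filter, and 1620 and 782.2 with no bound. With an array left out they were 281.4 to 315.1 and 210.7 to 251, and with a line left out 240.2 to 354.7 and 158.5 to 265.5. The distance difference was 0.03501 to 0.05439 with an array and 0.006529 to 0.09672 with a line left out.

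Lists called by origin were 0 with an estimated correlation, 0 by fry, 4 with every probe on its own, 2 to 3 with an array left out and 2 to 4 with a line left out (4 without NT.1, and 4 without FT.3, where the interferon list was not called). The endoderm list was gained without FT.1, NT.1, NT.1 replicate 2 or NT.2 replicate 1 and with every probe on its own, p53 targets without NT.1 or FT.3 and with every probe on its own, sex-linked markers and glycolysis without FT.3, and neuroectoderm without NT-LE. Lists called for NT-LE were 0 with an estimated correlation, 5 with no filter, 4 with the strict filter, 6 with every probe on its own and 3 to 5 with an array left out (5 without NT.1 replicate 1 or NT-LE replicate 3). The trophoblast list was gained with no filter, with the strict filter and without NT.1 replicate 1, NT.2 replicate 1 or NT-LE replicate 3. The p53 list was not called for NT-LE with chromosome 11 left out. The median line share of variance was 0.06742 with no filter and 0.1374 to 0.2048 with an array left out. The median origin share was 0.03141 with the strict filter, 0.008821 without the 3 arrays and 0 to 0.01977 with an array left out (0.01977 without FT.3 replicate 1).

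Among the 153 pairs of a gene and a contrast followed, 7 genes that passed in one of the fits compared turned in NT minus FT when 1 line was left out. Genes that passed in neither (11 moved, such as Dlk1) and genes followed only against all other lines (Slpi and Cyba) are not counted. Ccn2 NT minus FT ran from -0.9129 (without FT.1) to 1.437, and Lss NT minus FT from -0.002742 (without NT.1) to 0.4869. Krt18 NT minus FT ran from -0.8183 to 0.2367 and H2-K1 NT minus FT from -1.793 to 0.3455, both highest without NT.2. Without NT-LE, Trim6 NT minus FT was highest at 0.04577 (lowest -0.8259), Apoa2 NT minus FT at 0.5879 (lowest -1.181) and Ndufb10 NT minus FT at 0.4574 (lowest -1.65). The probes used were undetected for H2-K1 in NT.2 and for Trim6 and Apoa2 in NT-LE, so these values give only the direction.

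With a replicate block, the counts were 0, 3254, 23, 1978 and 1290 genes, 290.1 and 217.2 per pair, and 2 and 3 lists. Replicate numbers did not pair the arrays over all lines: over 45 pairs with the same number r ran from -0.515 to 0.42 (median -0.014), with 6 pairs above 0.1. Between NT.1 and NT-LE the same-numbered arrays had r of 0.292, 0.42 and 0.185, and the differently numbered ones -0.377 to 0.0944. Pairing of arrays between NT.1 and NT-LE is therefore not excluded. Signal over background limits genes near the floor, which have only bounds and whose differences shrink with a larger offset.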

Other observations

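Chromatin and DNA methylation genes, on a list fixed before the data were examined, had 8 members that rose, 3 that fell and 32 that did not pass of 43 in the 18-array fit of NT against FT lines (adjusted over the list alone 10 and 4, camera adjusted p = 0.341). The tests in this part were fixed in advance, except the look at the 3 splits that keep the NT lines whole. That look was added after the result was seen. The X-linked demethylase Kdm6a rose by 0.54 (SE 0.07), from 11.29, 11.20 and 11.49 in FT.1, FT.2 and FT.3 to 11.75, 11.75 and 12.10 in NT.1, NT.2 and NT-LE. Its lowest lines, FT.1 and FT.2, are those with Y-linked transcripts and no Xist signal, so sex and origin were not separated for it. Kdm6b, on chromosome 11, had a difference of -0.38 and did not pass without NT.2. Germ cell genes had 0 that rose and 5 that fell of 17 (adjusted over the list alone 0 and 5, adjusted p = 0.341), among them the X-linked Rhox5 (-1.02) and Tdrd5 (-0.32, and -0.03 without NT.2, where it did not pass). The X-linked Xlr4a was not above background in NT-LE, at least 2.37-fold below the FT lines. Of 20 BMP and Wnt targets 3 rose and 3 fell, and the same adjusted over the list alone (adjusted p = 0.982, median 0.05, mean 0.0037 and test pointing down). Id1 and Ccnd2 had differences of -0.71 and -0.58, and Lef1 and Nkd1 rose by 0.50 and 0.43, but Nkd1 did not pass without NT-LE (0.17). With lines as replicates 2 of these targets passed adjusted over the list alone and 0 over all genes. Since camera tests for a shift in 1 direction, it cannot decide on targets that move both ways. In fry for change in either direction, BMP and Wnt targets ranked ahead of all other lists, followed by germ cell genes. No call was made from that ranking. Of 28 activin, Nodal and FGF genes 5 rose and 4 fell, and the same adjusted over the list alone (adjusted p = 0.982), with Fgf15 at 0.49 (not passing without NT.2, at 0.33) and Dusp4 at -0.43.

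Metabolic and growth genes did not pass as lists by origin in the fit reported (without FT.3 the glycolysis and p53 lists passed). Glycolysis and hypoxia genes had 1 that rose and 5 that fell of 25 (adjusted over the list alone 1 and 6, camera adjusted p = 0.286), with the lactate transporter Slc16a3, on chromosome 11, at -0.88 and Ankrd37 at -0.64. Oxidative phosphorylation had 5 that rose and 6 that fell of 81 (adjusted over the list alone 4 and 6, adjusted p = 0.982), and cholesterol synthesis 3 and 0 of 17 (adjusted over the list alone 3 and 0, adjusted p = 0.982), with Msmo1 at 0.35 (0.15 and not passing without NT-LE). Insig1 was at 6.05 in FT.1, 6.99 in NT.2 and 6.80 in NT-LE and not above background in FT.2, FT.3 and NT.1. Targets of p53 had 1 and 5 of 20 (adjusted over the list alone 1 and 6, adjusted p = 0.16), and proliferation genes 4 and 3 of 25 (adjusted over the list alone 6 and 3, adjusted p = 0.424). In the comparison by origin the lists named so far in this part had an adjusted p of 0.985 with an estimated correlation. In NT-LE against NT.1 and NT.2, interferon and MHC genes had 4 that rose and 1 that fell of 27 (adjusted over the list alone 7 and 2, adjusted p = 0.0994), primed pluripotency genes 0 and 1 of 23 (adjusted over the list alone 0 and 1, adjusted p = 0.0914), and BMP and Wnt targets 4 and 0 of 20 (adjusted over the list alone 4 and 0, adjusted p = 0.152). With an estimated correlation their adjusted p was 0.74, 0.214 and 0.396, and all 3 lists passed with every probe on its own. The interferon list also passed without NT.1 repeat 1, NT-LE repeat 2 or NT-LE repeat 3, and the primed list with no filter or without NT-LE repeat 1.

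Other splits of the samples were compared with the real one. For origin with lines as replicates, the real split gave 0 genes by limma (2128 at an unadjusted p under 0.05, against 1783 at most in another split) and the highest other 1, with 10 of 10 splits as large. The 18-array fit gave 3340 genes against 2494 at most in another split, the count separating all lines 28 against 7, and the mean genes per pair between minus within origins 75.17 against 38.5, with 1 of 10 splits as large each time. Lists gave 2 against 7, with 8 of 10 splits as large, and without NT-LE the fit gave 2087 genes against 2357, with 2 of 10. Each pair of lines, in a fit of its 6 arrays, gave 65 to 538 genes against 0 in any other split, with 1 of 10 as large. In all of these, 10 splits are too few for a share under 0.05. For NT-LE against NT.1 and NT.2, in a fit of these 9 arrays alone, the real split gave 488 genes against 319, with 1 of 84 splits as large. Most of these splits mix repeats of a line, which puts line differences into the error and lowers their counts. The rank therefore says little on NT-LE as a line, since only 3 of the 84 splits keep lines whole, and these gave 228 genes for NT.1, 319 for NT.2 and 488 for NT-LE. The lists of that comparison gave 3 against 9, with 43 of 84 splits as large, so chance is not excluded for the number of lists.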
